A study of Mus musculus with 6 samples.

How the data were processed

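The series holds 6 RNA-seq libraries of the epithelial part of back skin, 3 from IL-33 KO and 3 from WT mice that all received 0.25% DNFB 3 times a week for 22 days. Genotype and replicate number were taken from the sample titles. The labels number the mice within each genotype and do not otherwise state that each library came from a separate animal, so p-values measure the spread between these libraries.

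The authors deposited a table of read counts per gene and a table of FPKM values for the same 35275 genes and 6 libraries. Per the submitters' processing notes, STAR, RSEM and the mm10 mouse genome were used, with no versions given. The deposited counts are whole numbers with no row for unassigned reads, and were used unchanged. The deposited FPKM values equal the count divided by the listed gene length and the column total to within a relative difference of 2.782e-07, so they hold the same measurement scaled by total counts. Per the file headers each gene comes with an Ensembl identifier, a symbol, a gene type and coordinates. Of these identifiers 34490 are also in GENCODE M21, and 99.9% of those overlap the position given there for the same genome build. How strand was treated in counting is not given in the sources used here, so reads of overlapping antisense genes may not be told apart. How reads that match close copies were divided is not given there either, which leaves the values of immunoglobulin variable segments, Lce1, Stfa and Serpinb3 genes uncertain.

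Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the genotype as group at its defaults, which left 15720 genes. Library sizes were scaled by TMM, and the genotype effect was tested with the quasi-likelihood F test (glmQLFit with robust=FALSE, glmQLFTest), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes were derived from the F statistic. The common dispersion corresponded to a biological coefficient of variation of 21.3%. CPM values are counts divided by the TMM-scaled library size, in the usual unit of edgeR. A ratio against a genotype with 1 to 3 counts is given with a 95% exact binomial interval of its counts, which covers counting error only, since reads without molecular identifiers are not independent molecules.

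Before the data were examined, the test, the other settings named below and 31 gene lists with 631 symbols were fixed, the lists from textbook knowledge of skin, immune cells, the IL-33 and TGF-beta/SMAD pathways and other tissues that a skin piece can hold. Of the symbols 624 were matched to the table, 9 of them through another symbol or identifier. The 30 lists with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 and adjustment over the lists. The chromosome 19 neighbour list was kept as fixed, although its member Kdm4c lies on chromosome 4 in the deposited table. Each list was tested again with an estimated correlation and with fry. For each list the number of members that pass over all genes and that pass when adjusted over the list alone was counted. Genes were named by a rule fixed in advance: Il33, then the 12 largest changes in each direction among genes that pass, or, with fewer than 10 passing in a direction, the 5 with the smallest p, and in each list up to 4 members that pass or otherwise the 2 with the smallest p. Other genes named in the text were chosen after their values were seen.

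Depth was 20459574 to 24359612 counts per library. On data simulated from the means and library sizes of these libraries, with 15720 genes per step and known changes, the edgeR test recovered 6.8% of genes changed 1.5-fold, 45.2% of those changed 2-fold, 92.4% of those changed 4-fold and 96.8% of those changed 8-fold, with 8.77% false calls among its calls. DESeq2 1.42.0 recovered 18%, 64%, 92.4% and 96% with 24.9% false calls. In the simulated lists, 5 of 5 moved lists and 0 of 5 unmoved lists were higher at an unadjusted p under 0.05 in camera. Calls in the lower direction were not counted. Simulated genes varied independently, while the estimated correlation was 0.69 in the hair follicle list and 0.81 in the skeletal muscle list. The simulation therefore does not check camera for lists whose genes vary together.

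The alternatives tried were other size factors (RLE, upper quartile, total counts), other filters, DESeq2, limma-voom, robust edgeR, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) of genes with an FPKM of at least 1 in 3 libraries or unfiltered, the replicate number as a block, each library left out in turn, other thresholds, and removal of hair follicle, skeletal muscle and adipocyte genes. No pair of libraries agreed within sampling noise, as the chi-square of their counts was at least 31.7 per degree of freedom for every pair. A test of a further explanation for the antibody transcripts is not reported here. Figures were drawn with matplotlib 3.10.9.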

Results

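RNA was sequenced in 6 libraries from the epithelial part of back skin of C57BL/6 mice, 3 libraries from mice lacking interleukin-33 (IL-33 KO) and 3 from wild-type mice (WT). IL-33 is a cytokine of the IL-1 family that is stored in the nuclei of epithelial cells and released when they are damaged. All mice had been painted on the back with 0.25% dinitrofluorobenzene (DNFB), a contact allergen that causes dermatitis, 3 times a week for 22 days, so the libraries hold inflamed skin in both genotypes and no untreated skin. The total count was 22096989, 23671769 and 20459574 in IL-33 KO 1, 2 and 3. It was 21312392, 24359612 and 24238735 in WT 1, 2 and 3. Of 35275 listed genes, 15720 had enough counts to be tested, and these took 99.9% of all counts. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together had 0 to 2 counts in each library.

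The single comparison of the design asked which genes differ between IL-33 KO and WT skin under chronic allergen exposure. Il33 itself, the deleted gene, was nearly absent from the IL-33 KO libraries, at 0.782 ± 0.217 CPM (counts scaled to library size; SD, n = 3) against 147.6 ± 44.3 (SD, n = 3) in WT. Erdr1, erythroid differentiation regulator 1, and Fgfbp3, a carrier protein of fibroblast growth factors, were the genes that rose in IL-33 KO skin. Beyond these 3 genes, the hair follicle, skeletal muscle, melanocyte and Schwann cell, adipocyte, B and plasma cell, NK and cytotoxic, and interferon-stimulated lists were higher as groups in IL-33 KO. The epidermal differentiation, wound keratinocyte, IL-17 and IL-36, NF-kB and inflammatory cytokine, immediate early, mast cell, and fibroblast lists were lower as groups. These 14 group calls, 7 in each direction, come from camera with a preset correlation between genes, and 0 of them hold with an estimated correlation (smallest adjusted p = 0.588 with an estimated correlation). The adjustment gave most of these lists the same value of 0.588. Before adjustment the smallest p in camera with an estimated correlation was 0.0600, for the hair follicle list. No member of any of these lists passed the test over all genes.

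Il33 (ENSMUSG00000024810, mm10 chromosome 19, 29925114 to 29960718, plus strand) had 21, 22 and 11 counts in IL-33 KO 1, 2 and 3 and 3906, 3086 and 2817 in WT 1, 2 and 3. The IL-33 KO level was 0.530% of the WT level, a log2 fold change of -7.54 ± 0.32 (SE) with an adjusted p of 1.755e-04 in edgeR's quasi-likelihood test. In the deposited FPKM values Il33 stood at 0.317 ± 0.0914 in IL-33 KO and 55.8 ± 14.2 in WT (SD, n = 3). The libraries thus carry the Il33 levels that their genotype labels name. The exact permutation test of the 6 values gave a two-sided p of 0.1, the smallest that 3 against 3 allows.

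In the edgeR test 3 genes passed an adjusted p of 0.05, 2 higher and 1 lower in IL-33 KO. Erdr1 (listed on chromosome Y, 90784738 to 90816464) had 841 counts over the IL-33 KO libraries and 1 count over the WT libraries, a ratio of 841 with a 95% exact binomial interval of 151 to 33258 that covers counting error only. Its adjusted p in edgeR was 0.00231. Erdr1 lies in the region that the sex chromosomes share, and its reads can come from either chromosome. Fgfbp3 (chromosome 19, 36917550 to 36919615) stood at 23.5 ± 0.921 CPM in IL-33 KO and 6.52 ± 0.906 in WT, a log2 fold change of 1.85 ± 0.15 (SE). Its adjusted p in edgeR was 0.0105, and it was higher in 3 of 3 IL-33 KO libraries than in any WT library. Il33 and Erdr1 passed in each edgeR fit that left out 1 library, whereas Fgfbp3 missed the threshold in 4 of the 6, with adjusted p of 0.118 without IL-33 KO 1, 0.0618 without IL-33 KO 3, 0.0532 without WT 1 and 0.0774 without WT 2. At an unadjusted p under 0.05 there were 1418 genes, 765 higher and 653 lower, where chance gives 786. This count was 716 of 15941 tested genes without IL-33 KO 1, 943 without WT 2 and 2750 without WT 3, and its balance moved to 835 higher and 538 lower with upper quartile scaling and to 906 and 334 with total counts. The same counts gave 233 genes in DESeq2, 186 higher and 47 lower, among them the 3 edgeR genes. The edgeR count was 10 without IL-33 KO 2, 5 without IL-33 KO 3 and 24 without WT 3.

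**Figure D1:**
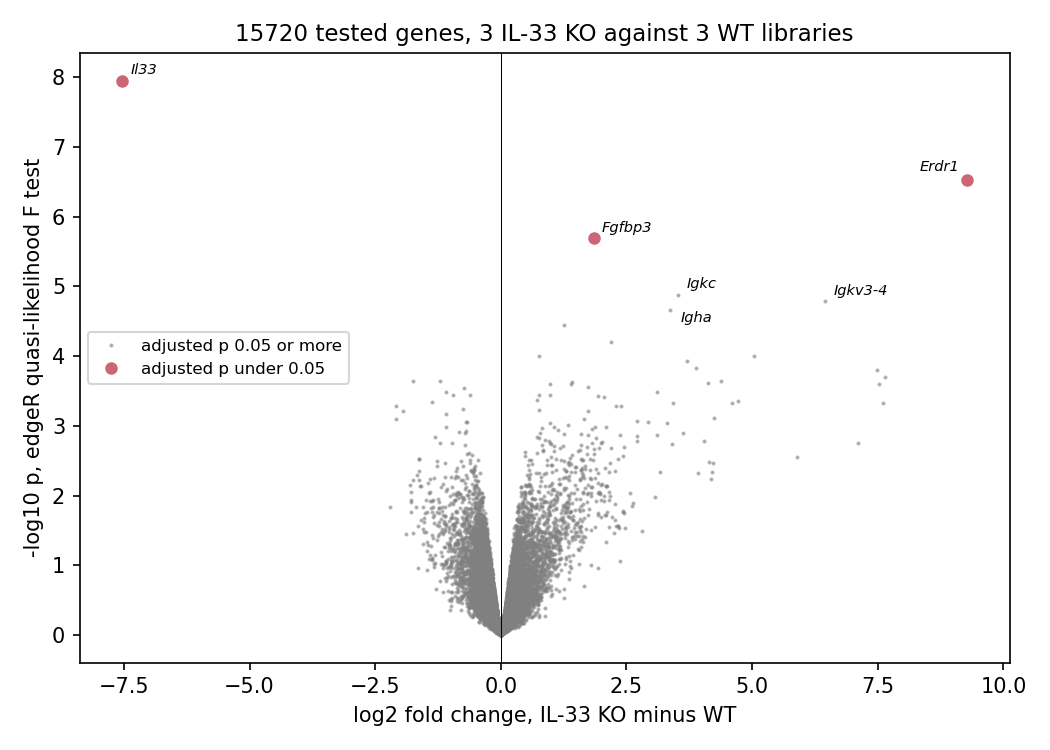
Each point is one of 15720 tested genes, with the log2 fold change (IL-33 KO minus WT) on the horizontal axis and the -log10 of the unadjusted p of the edgeR test on the vertical axis. Il33, Erdr1 and Fgfbp3, in red, have an adjusted p under 0.05, and Igkc, Igkv3-4 and Igha lie just short of it.

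Antibody genes came next in rank, just short of the threshold, and their calls depended on the setting. Igkc, the kappa light chain constant region, was measured at 142 ± 57.3 CPM in IL-33 KO and 12.3 ± 3.88 in WT (SD, n = 3), a log2 fold change of 3.52 ± 0.37 with an adjusted p of 0.0513 in edgeR. Igha, the constant region of immunoglobulin A, was measured at 192 ± 75.5 CPM against 18.5 ± 6.40 (log2 fold change 3.37 ± 0.38, adjusted p 0.0567). The variable segment Igkv3-4 had 121 counts over the IL-33 KO libraries and 1 over WT, a ratio of 121 with a counting interval of 21.3 to 4818 and an adjusted p of 0.0515 in edgeR. Of 43 tested immunoglobulin gene segments, 37 were higher and 6 lower in IL-33 KO, with a median log2 fold change of 2.46, and 24 were higher and 3 lower in each IL-33 KO library than in each WT library. Chance gives 10% without overlap, in either direction, and 13.9% of all tested genes had none. The file lists 432 immunoglobulin genes, and most had too few counts to be tested. Segments nearly absent from WT, such as Igkv3-4, passed the filter through the IL-33 KO libraries alone. The split and the median therefore hold only for the segments that passed the filter. Variable segments are close copies of each other, so how their reads were divided among them is uncertain. In DESeq2 40 immunoglobulin genes passed, all higher in IL-33 KO. Igkc passed with upper quartile (adjusted p 0.0464) and total-count scaling (0.0405), in limma-voom (0.0366), with log2(FPKM + 1) (0.0273) and without IL-33 KO 3 (0.0139) or WT 3 (0.0451). It did not pass in robust edgeR (0.154), nor without IL-33 KO 1 (0.145), IL-33 KO 2 (0.0771), WT 1 (0.130) or WT 2 (0.338). Among genes with the smallest p in the lower direction, none but Il33 passed over all genes. The monocyte chemokine gene Ccl2 had 6.52 ± 1.20 CPM in IL-33 KO and 15.1 ± 2.00 in WT (SD, n = 3; adjusted p 0.182 in edgeR), and the insulin-like growth factor binding protein gene Igfbp2 had 65.2 ± 11.3 and 220 ± 87.2 (0.182). The matricellular protein gene Cyr61 had 33.4 ± 1.73 and 55.2 ± 5.57 (0.187) and the serpin gene Serpinb10 had 7.23 ± 0.698 and 15.4 ± 2.64 (0.187), each with all 3 IL-33 KO libraries below all 3 WT libraries.

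**Figure D2:**
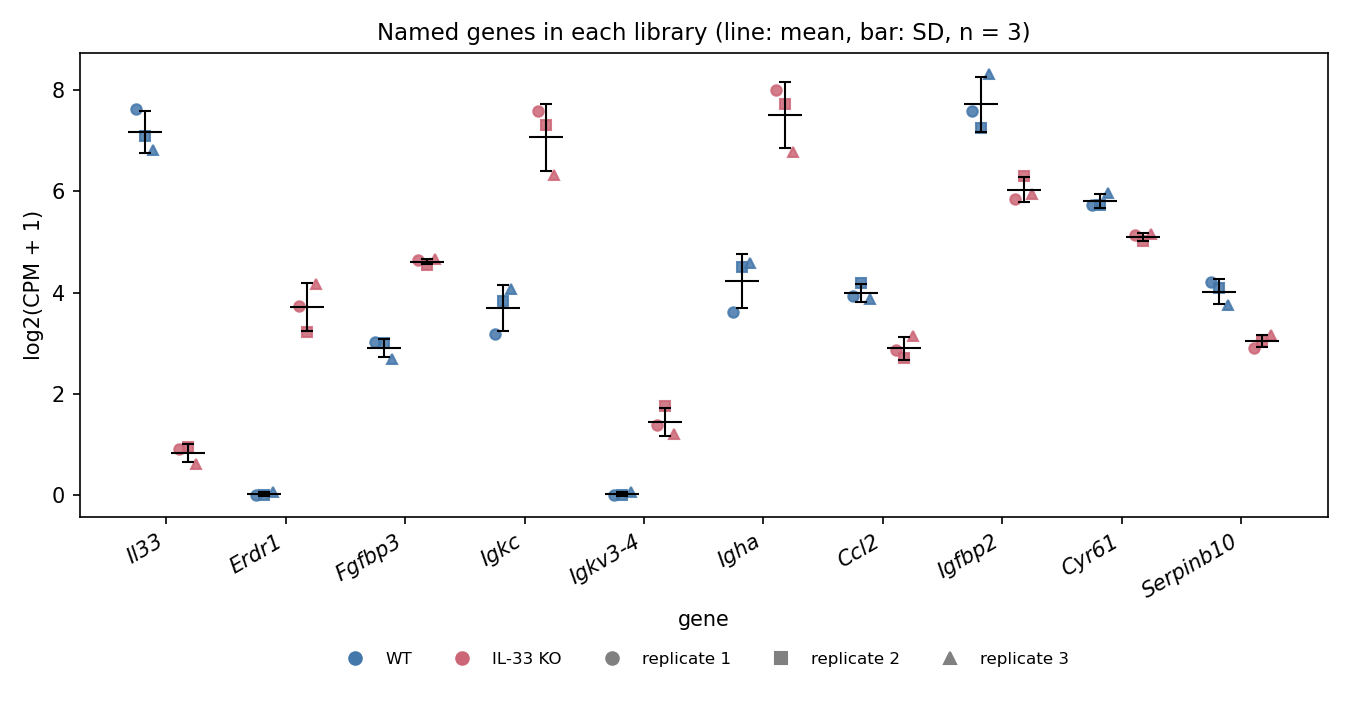
Levels of the 10 named genes in each library as log2(CPM + 1), with WT in blue and IL-33 KO in red, symbols for replicates 1 to 3, a horizontal line at the mean and bars of 1 SD. For each of the 10 genes the 3 IL-33 KO libraries lie apart from the 3 WT libraries, with Il33, Ccl2, Igfbp2, Cyr61 and Serpinb10 lower and the others higher in IL-33 KO.

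The hair follicle list showed the most uniform difference. All 36 tested members were higher in IL-33 KO, 29 of them without overlap between the genotypes where chance gives 10% in either direction, with a median log2 fold change of 1.77. The list passed in camera with an adjusted p of 1.132e-27, and had an adjusted p = 0.588 with an estimated correlation. None of its members passed over all genes in edgeR, 17 passed in DESeq2, and 33 passed when adjusted over the list alone. Krt72, a keratin of the inner root sheath, stood at 452 ± 121 CPM in IL-33 KO and 98.9 ± 34.6 in WT (SD, n = 3), and Dlx3, a homeobox regulator of hair shaft formation, at 148 ± 43.7 and 55.6 ± 8.28. The mean level of the list in WT 3 lay 0.07 below the mean of all 6 libraries on the log2 scale, against -0.86 in WT 1 and -1.70 in WT 2. The melanocyte and Schwann cell list moved in the same direction (10 of 15 members higher, camera adjusted p 0.00165, and adjusted p = 0.588 with an estimated correlation). Of these 15 genes 6 passed when adjusted over the list alone, all higher, including the melanosomal transporter gene Slc45a2 at 3.82 ± 1.23 against 1.24 ± 0.566 CPM and Mlana, which is also in the chromosome 19 neighbour list of Il33, at 9.64 ± 3.91 against 3.76 ± 0.609. The adipocyte list was higher in 16 of 16 members, with Lpl, lipoprotein lipase, at 398 ± 23.6 against 212 ± 122 CPM and Retn, resistin, at 17.9 ± 5.66 against 8.30 ± 5.30. Its camera adjusted p was 1.289e-04, with an adjusted p = 0.588 with an estimated correlation, and no adipocyte gene passed when adjusted over the list alone. WT 1 stood apart: the mean level of the list was -1.75 there on the log2 scale, relative to all 6 libraries, and 0.62 in WT 2, above the 0.37 of IL-33 KO 2 and the 0.15 of IL-33 KO 3. Without WT 1 the camera adjusted p was 0.0372.

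Skeletal muscle genes were higher in 14 of 14 tested members, and 13 passed when adjusted over the list alone, but the difference came from IL-33 KO 1 and 3. The list has 24 symbols, and the others had too few counts to be tested. A member nearly absent from WT, such as Acta1, was kept through the IL-33 KO libraries alone. Acta1, skeletal muscle actin, was at 38.1, 0.548 and 60.8 CPM in IL-33 KO 1, 2 and 3 and at no more than 0.353 CPM in the WT libraries, and Ryr1, the calcium release channel of muscle, was at 8.35, 5.06 and 16.1 against at most 3.11. The list had a camera adjusted p of 1.385e-08 and an adjusted p = 0.588 with an estimated correlation. The B and plasma cell list had 11 of 14 members higher (camera adjusted p 3.174e-06, adjusted p = 0.588 with an estimated correlation), and 7 passed when adjusted over the list alone, all higher. Besides Igkc, its member Igj, the joining chain of secreted antibody, stood at 93.6 ± 50.1 CPM in IL-33 KO and 6.31 ± 3.73 in WT. The NK and cytotoxic lymphocyte list had 10 of 12 members higher (camera adjusted p 0.00382, adjusted p = 0.588 with an estimated correlation). It had log2 fold changes of 0.82 ± 0.34 (SE) for the transcription factor gene Tbx21 and 1.04 ± 0.46 for Eomes. This list missed the threshold without IL-33 KO 2, without WT 2 and with log2(FPKM + 1) (camera adjusted p 0.0535, 0.192 and 0.0768). The interferon-stimulated list had 24 of 30 members higher (camera adjusted p 0.0103, adjusted p = 0.743 with an estimated correlation). Rsad2 was at 15.4 ± 3.89 against 10.1 ± 1.26 CPM and Irf7 at 41.2 ± 3.85 against 30.1 ± 5.92. It missed the threshold without IL-33 KO 2 (0.286) and without IL-33 KO 3 (0.0764), and its direction turned without WT 2 (0.794). No NK or interferon gene passed when adjusted over the list alone.

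**Figure D3:**
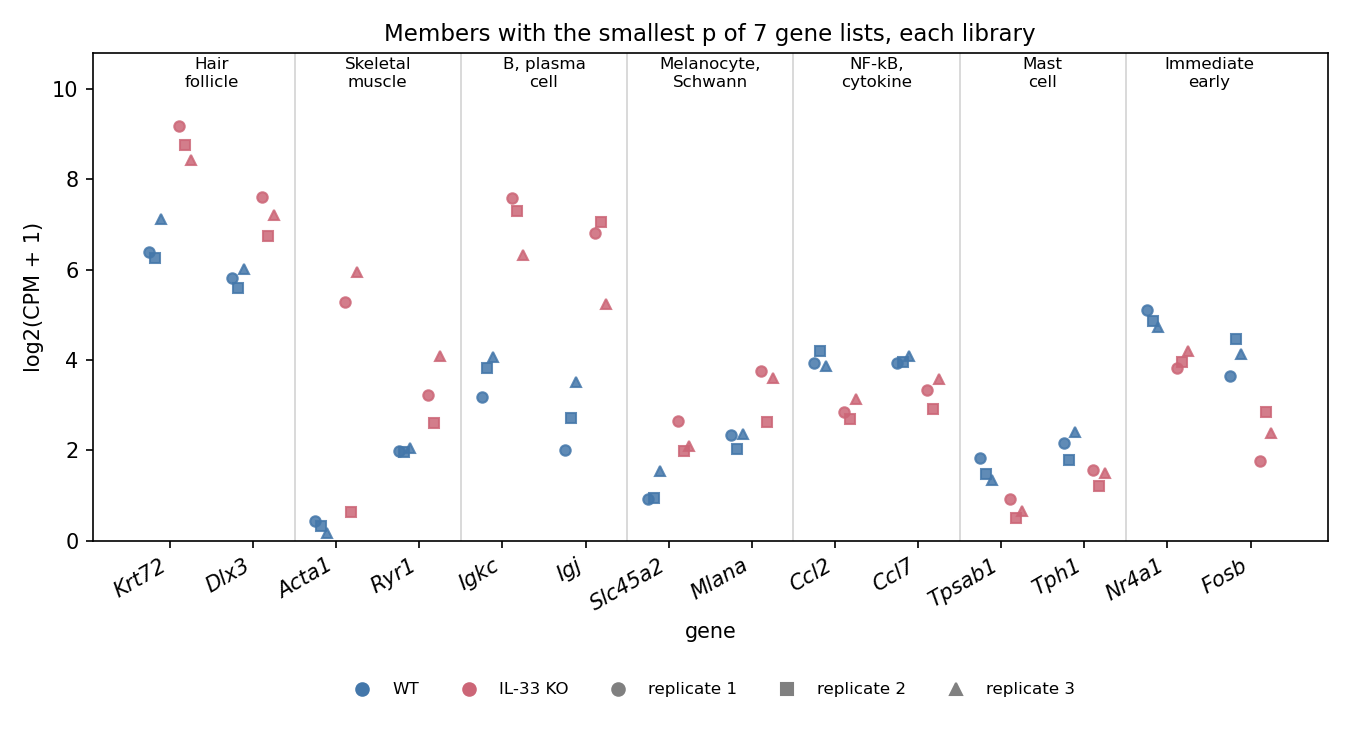
Levels in each library, as log2(CPM + 1), of the 2 members with the smallest p of 7 gene lists, with WT in blue, IL-33 KO in red and symbols for replicates 1 to 3. Acta1 is high in IL-33 KO 1 and 3 and near the WT level in IL-33 KO 2, and Krt72, Dlx3, Igkc and Igj are higher in the 3 IL-33 KO libraries than in the 3 WT libraries.

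Of the 7 lists that were lower in IL-33 KO, WT 1 had the highest mean level of all but the mast cell and fibroblast lists. In WT 3 the epidermal differentiation list stood at -0.28, below IL-33 KO 2 (0.14) and IL-33 KO 3 (-0.21). The wound list stood at -0.42 there, below IL-33 KO 2 (-0.24) and IL-33 KO 3 (0.023). The IL-17 and IL-36 list (-0.36) and the NF-kB list (-0.21) were also lower in WT 3 than in IL-33 KO 3 (-0.0091 and 0.23). For the NF-kB list both WT 2 (-0.19) and WT 3 lay below IL-33 KO 2 (-0.15) and IL-33 KO 3. These levels are log2 values relative to the mean of all libraries. The epidermal differentiation and barrier list was lower in 29 of 31 members (median log2 fold change -0.48, camera adjusted p 1.718e-05, adjusted p = 0.588 with an estimated correlation). The cornified envelope gene Lce1b was at 91.6 ± 35.3 CPM in IL-33 KO and 214 ± 94.4 in WT and Lce1a1 at 144 ± 48.8 and 323 ± 145. The wound and hyperproliferative keratinocyte list was lower in 24 of 24 members (median log2 fold change -0.62, camera adjusted p 6.646e-05, adjusted p = 0.588 with an estimated correlation). Serpinb3a was at 23.6 ± 6.98 against 73.4 ± 37.7 CPM and Stfa3 at 720 ± 156 against 1381 ± 610. Lce1, Serpinb3 and Stfa genes belong to families of close copies, and their counts share that uncertainty. The IL-17 and IL-36 epidermal response list was lower in 17 of 20 tested members (median log2 fold change -0.93, camera adjusted p 5.855e-04, adjusted p = 0.588 with an estimated correlation). Il17a, Il17f, Il22 and Il12b had too few counts to be tested. The cytokine gene Il24 was at 5.13 ± 1.55 against 13.6 ± 6.49 CPM and the chemokine gene Ccl20 at 1.17 ± 0.146 against 3.00 ± 1.72. No gene of these 3 lists passed when adjusted over the list alone. With the hair follicle list mean as a covariate, chosen after seeing the data, Lce1b, Lce1a1 and Stfa3 turned direction (log2 fold changes of 0.37, 0.38 and 0.33), and Serpinb3a (-0.57) and Il24 (-1.48) did not. The turned values did not pass the threshold. The hair follicle list mean was itself higher in each IL-33 KO library (at least 0.58) than in each WT library (at most -0.07). This fit thus separates it poorly from genotype. The NF-kB target and inflammatory cytokine list was lower in 23 of 23 members (camera adjusted p 1.289e-04, adjusted p = 0.588 with an estimated correlation), and Ccl2, Ccl7, Nfkb2 and Cxcl1 passed when adjusted over the list alone. Ccl7, like Ccl2 a monocyte chemokine, stood at 8.86 ± 2.18 CPM in IL-33 KO and 14.8 ± 0.980 in WT. Without WT 1 the NF-kB, IL-17 and IL-36, and wound lists missed the threshold, with camera adjusted p of 0.400, 0.143 and 0.0897.

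Immediate early and heat shock genes were lower in 17 of 18 members (camera adjusted p 7.124e-05, adjusted p = 0.588 with an estimated correlation), and 4 passed when adjusted over the list alone: Nr4a1, Fosb, Fos and Dusp1. Nr4a1, an orphan nuclear receptor gene, stood at 15.0 ± 2.19 CPM in IL-33 KO and 28.9 ± 3.92 in WT, and Fosb, a component of AP-1, at 4.26 ± 1.88 and 16.3 ± 4.78. Mast cell genes were lower in 13 of 15 members, 8 of them without overlap (camera adjusted p 1.088e-04, adjusted p = 0.588 with an estimated correlation). The tryptase gene Tpsab1, at 0.629 ± 0.236 against 1.97 ± 0.538 CPM, passed when adjusted over the list alone, and Tph1, tryptophan hydroxylase, stood at 1.69 ± 0.339 against 3.41 ± 0.928. The fibroblast and extracellular matrix list was lower in 23 of 27 members, with Mmp2 at 247 ± 17.5 against 345 ± 27.9 CPM and Lum, lumican, at 250 ± 13.7 against 395 ± 139. Its camera adjusted p was 6.133e-04, with an adjusted p = 0.689 with an estimated correlation, no member passed when adjusted over the list alone, and without WT 3 the camera adjusted p was 0.317.

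**Figure D4:**
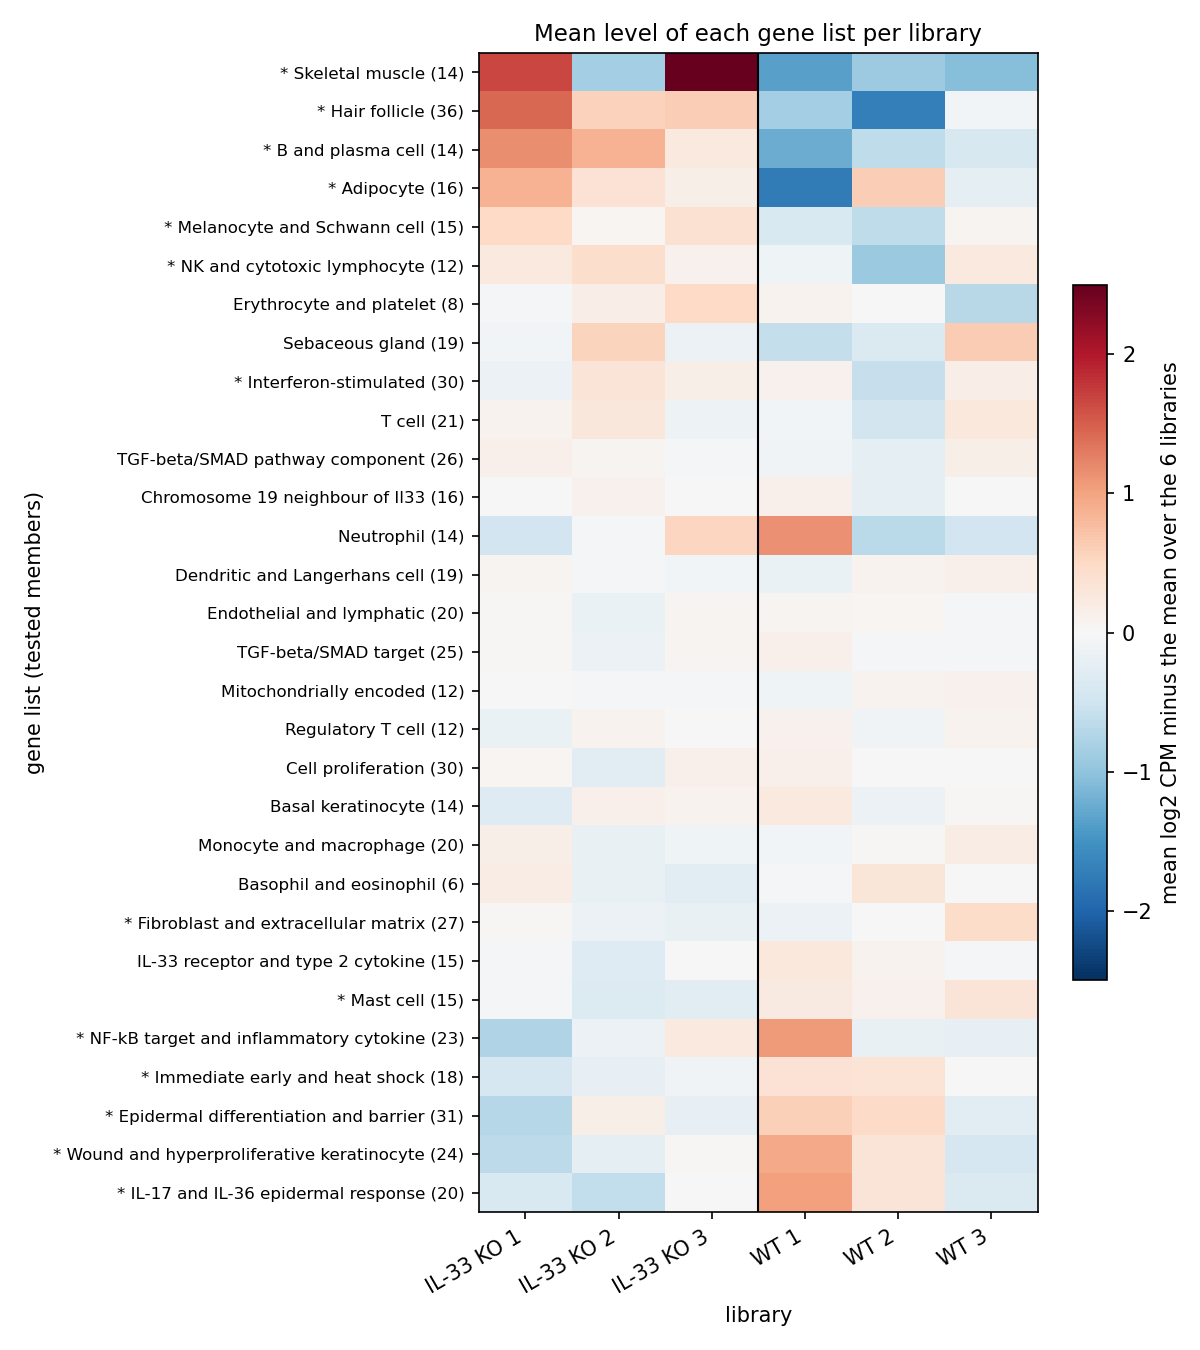
Mean level of the tested members of each gene list in each library, as log2 CPM minus the mean over the 6 libraries (color), with the number of tested members in brackets and a star where the camera adjusted p is under 0.05. Skeletal muscle is high in IL-33 KO 1 and 3 alone, and hair follicle genes are highest in IL-33 KO 1 and lowest in WT 2.

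The IL-33 receptor and type 2 cytokine list did not pass (11 of 15 tested members lower, camera adjusted p 0.0893, adjusted p = 0.588 with an estimated correlation), but did with total counts (0.0374) and without WT 2 (0.0270). Of its 24 symbols 15 were tested. Il5, Il9, Il13, Il31, Il25, Ccl17, Ccl1, Retnla and Chil4 had too few counts, so the list says nothing of them. Its member Gata3, a transcription factor of type 2 lymphocytes that is also in the hair follicle list, stood at 107 ± 11.8 CPM in IL-33 KO and 63.4 ± 11.3 in WT and passed when adjusted over the list alone, and Chil3, a chitinase-like protein of macrophages, stood at 15.6 ± 4.25 and 27.3 ± 7.88. The TGF-beta/SMAD pathway component list was split between 13 members higher and 13 lower (camera adjusted p 0.378), with the inhibitory Smad6 at 14.9 ± 5.25 against 7.35 ± 0.643 CPM and Smad5 at 90.6 ± 5.04 against 68.9 ± 12.9. The median log2 fold change of this list was -2.145e-04 while its mean was 0.08. Its target list had 15 of 25 members lower (camera adjusted p 0.220). Of these, Cyr61 passed in the lower direction and Bambi, a decoy receptor gene, in the higher direction when adjusted over the list alone, Bambi at 29.8 ± 11.8 against 11.4 ± 3.89 CPM. The threshold was not passed in camera by basophil and eosinophil (adjusted p 0.557), neutrophil (0.740), monocyte and macrophage (0.168), dendritic and Langerhans cell (0.763), T cell (0.378), regulatory T cell (0.530), basal keratinocyte (0.496), cell proliferation (0.328), sebaceous gland (0.496), endothelial and lymphatic (0.670), erythrocyte and platelet (0.130), mitochondrially encoded (0.604) and chromosome 19 neighbour (0.691) genes. Some of them passed when 1 library was left out: monocyte and macrophage without IL-33 KO 1 (0.00726) or WT 1 (0.0340), neutrophil (0.0103) and erythrocyte and platelet (0.0463) without WT 1, proliferation without IL-33 KO 3 (0.0212), and T cell (0.0312) and sebaceous gland (0.00424) without WT 3. In these lists no gene passed when adjusted over the list alone. The sebaceous gland list had a median log2 fold change of -0.07 and a mean of 0.12, and the chromosome 19 neighbour list -0.05 and 0.03, so that median and mean differ in sign. Of the sex-linked list Xist alone had enough counts, at 406 ± 60.5 CPM in IL-33 KO and 370 ± 84.1 in WT (adjusted p 0.846 in edgeR).

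Over all tested genes the libraries did not separate cleanly by genotype. The Spearman correlation of log2 CPM was 0.983 ± 0.00429 (SD) over the 6 pairs within a genotype and 0.978 ± 0.00760 over the 9 pairs between genotypes, and these correlations are across genes, which are not independent replicates. The first principal component of the 1000 most variable genes held 51.6% of their variance and placed IL-33 KO 1, 2 and 3 at -31.1, -16.1 and -12.1, WT 1 and 2 at 32.1 and 28.6, and WT 3 at -1.46, nearest to the IL-33 KO libraries. Krt14, a basal keratinocyte keratin, took 1.36%, 1.82% and 1.97% of all counts in IL-33 KO 1, 2 and 3 and 2.68%, 2.40% and 1.64% in WT 1, 2 and 3. The labels name no batch or day of collection.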

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

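The tests chosen after seeing the data were edgeR with adjusted deviances, the edgeR likelihood ratio test, the hair follicle list mean as a covariate, and DESeq2 without WT 3. Il33 kept its direction and stayed past the threshold under every setting run (adjusted p at most 0.0194). The edgeR count of 3 genes (2 higher, 1 lower) became 5 (4 higher, 1 lower) with upper quartile, total-count scaling or a filter of at least 1 CPM in 3 libraries, 6 without hair follicle, muscle and adipocyte genes, 33 with no filter, 7 at an adjusted p under 0.1, 11 in limma-voom, 15 with log2(FPKM + 1), 11 with log2(FPKM + 0.1), 6 with unfiltered log2(FPKM + 1) and 233 in DESeq2. The added tests gave 7 with adjusted deviances, 200 with the likelihood ratio test, 1 with the hair follicle covariate and 877 in DESeq2 without WT 3. All 3 genes were among the calls of each of these settings except the covariate, which kept Il33 alone. There the log2 fold change of Erdr1 was 9.11 ± 1.14 (SE) against 9.28 ± 0.60 without the covariate, and that of Fgfbp3 was 2.09 ± 0.29 against 1.85 ± 0.15, so the calls ended through larger errors. Igkc and Igkv3-4 were the added calls with upper quartile, total-count scaling and the CPM filter, and antibody genes were 6 of the 11 calls in limma-voom and 11 of the 15 with log2(FPKM + 1). Igkc missed the threshold with the block (0.384), unfiltered log2(FPKM + 1) (0.138) and the covariate (0.999), and ranged from 3.275e-22 to 0.999 over all settings. Genes at an unadjusted p under 0.05 numbered 830 with the block and 476 with the covariate, against 1418. Leaving out 1 library gave 2 to 24 genes. The 24 without WT 3 included the epidermal genes Lce1k, Klk12 and Klk14, lower, and Krt72, higher, and the 10 without IL-33 KO 2 included 7 muscle genes. The cause of the other changes was not tested. Deviations of same-numbered libraries correlated at -0.26, -0.12 and -0.38. With 3 per genotype this cannot exclude a shared batch. The replicate block gave 2 genes and Fgfbp3 an adjusted p of 0.334 (2.011e-18 to 0.467 over all alternatives). The block changed no call of a gene list. Against 14 lists past the threshold in camera, 0 passed with an estimated correlation, 0 in fry for movement in a single direction (smallest adjusted p 0.246) and 3 in fry for change in either direction (adjusted p 0.0356 each), of which mast cell and B and plasma cell are among the 14 and TGF-beta/SMAD target is not. Otherwise 12 to 15 lists passed, with 11 to 14 of the 14 among them. The 11 were without WT 1, where the NF-kB, IL-17 and IL-36, and wound lists missed the threshold and the neutrophil, monocyte and macrophage (0.0340), and erythrocyte and platelet (0.0463) lists passed. With the hair follicle covariate 10 named genes turned direction, none past the threshold: Alox15 (0.12), Trbc2 (0.48), Eomes (-0.40), Igfbp3 (0.020), Lce1b (0.37), Lce1a1 (0.38), Stfa3 (0.33), Fads2 (-0.030), Mc5r (-0.57) and Xist (-0.53, log2 fold changes). Lists whose direction turned when 1 library was left out had camera adjusted p from 6.619e-05 to 0.794 (interferon), 0.0103 to 0.915 (neutrophil), 0.401 to 0.981 (dendritic), 0.0312 to 0.981 (T cell), 0.0736 to 0.775 (basal keratinocyte), 0.0212 to 0.775 (proliferation), 0.00424 to 0.952 (sebaceous), 0.307 to 0.847 (endothelial) and 0.211 to 0.965 (chromosome 19 neighbour). Without WT 1 the neutrophil list was higher in IL-33 KO at 0.0103. With log2(FPKM + 1) the regulatory T cell (0.397) and chromosome 19 neighbour (0.968) lists turned. The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 3 edgeR genes and the highest other split 0. In DESeq2 these were 233 and 718 genes and in camera 14 and 16 lists, with 1, 2 and 2 splits as large. The split with 718 genes set IL-33 KO 1, IL-33 KO 2 and WT 3 against the others and had 2880 genes at an unadjusted p under 0.05 in edgeR, against 1418 for the real one, which points to a structure of the libraries other than genotype.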

Other observations

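Of the tests below, those on the fibroblast list, the Il33 level of WT 3, follicle regulators, summed immunoglobulin counts and the neighbourhood of Il33 were chosen after the values they measure had been seen at least in part. Those on Igkc per library, Ide and Nnt were set after the genotype difference they address was seen. Igkc is itself among the genes that showed this difference, and none of these tests is taken as a blind prediction. The genes named here outside the fixed lists were chosen after their values were seen. Stra6, a retinol transporter gene, had a log2 fold change of 1.26 ± 0.15 (SE), with an adjusted p of 0.0815 in edgeR and 1.002e-07 in DESeq2, and Ufd1l, a ubiquitin-dependent degradation gene, stood at 89.3 ± 2.26 CPM in IL-33 KO and 53.0 ± 3.10 in WT (SD, n = 3; 0.159 in edgeR and 2.920e-05 in DESeq2). Il18, an epidermal cytokine gene related to Il33, stood at 28.2 ± 6.86 and 55.9 ± 17.3 CPM, with all IL-33 KO libraries below all WT libraries and an adjusted p of 0.402 in edgeR and 0.0342 in DESeq2. Other genes known from plasma cells differed among themselves: Mzb1 stood at 2.52 ± 1.08 against 0.221 ± 0.172 CPM and Pou2af1 at 2.48 ± 0.983 against 0.576 ± 0.163, Tnfrsf17, too low to be tested, had 34 counts against 4, and Derl3 stood at 0.900 ± 0.198 against 0.945 ± 0.398.

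WT 3, the library nearest to IL-33 KO on the first principal component, had 119.7 times the Il33 of the highest IL-33 KO library. This argues against WT 3 being a mislabelled IL-33 KO library. Such a library would lessen the rise of hair follicle and skeletal muscle genes in IL-33 KO, so the test does not bear on its cause. A difference in hair cycle stage between the mice stays open as a candidate explanation. The 7 regulators Lef1, Shh, Msx1, Msx2, Foxn1, Hoxc13 and Dlx3 were all higher (median log2 fold change 2.01, range 0.82 to 2.34), but they belong to the list already seen to be higher throughout, so this test was bound to come out so. More deep tissue in the dissected piece stays open, because the fibroblast list, which deeper dermis would raise, differed by -0.20 ± 0.19 (SE) on the log2 scale and its genes are abundant in every library. The lists parted in IL-33 KO 2, with mean levels of 0.58 for hair follicle and -0.85 for skeletal muscle genes. These levels are log2 values relative to the mean of all libraries. A single explanation therefore need not hold for both lists. An effect of Il33 loss on follicle growth was not tested apart from these explanations.

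For the higher antibody transcripts in IL-33 KO, the rise of Igkc did not rest on a single IL-33 KO library. The lowest IL-33 KO library had 5.02 times the Igkc of the highest WT library. Igkc was named for its small p, which favours genes high in all IL-33 KO libraries. This ratio therefore describes Igkc and does not test the other antibody genes. Reads moved between similar segments would leave the sum as it was. The summed immunoglobulin CPM of the lowest IL-33 KO library was 2.28 times that of the highest WT library. This sum, on average 498 CPM in IL-33 KO and 105 in WT, includes the constant regions Igkc and Igha, already seen to be higher. Their means were 142 and 192 CPM in IL-33 KO and 12.3 and 18.5 in WT. The ratio therefore does not decide whether reads were shared among variable segments. More antibody-secreting cells in IL-33 KO skin, with cause unknown, is a hypothesis that may fit these values, and neither other tissue in the dissected piece nor differences in housing or age between the genotypes are weighed here.

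Erdr1 and Fgfbp3 may mark genetic background. C57BL/6 substrains differ at Nnt, which is truncated in C57BL/6J, and Nnt was lower in IL-33 KO by a log2 fold change of -1.10 without overlap (9.50 ± 0.424 against 20.3 ± 5.24 CPM; adjusted p 0.231 in edgeR and 0.00115 in DESeq2), in line with mice of different substrains. A copy number difference of the interval with Fgfbp3 and Ide, known to vary among C57BL/6J mice, is a candidate explanation for Fgfbp3, since its neighbour Ide had a log2 fold change of 0.76 without overlap (adjusted p 0.476 in edgeR), smaller than the 1.85 of Fgfbp3. For a block of chromosome 19 carried with the knockout allele, 14 of 110 genes within 10 Mb of Il33 (12.7%) had p under 0.05 against 8.99% of other genes (Fisher's exact test, one-sided p 0.118), which leaves it undecided. Fgfbp3, whose rise prompted the test, and Ide are among these 14 genes, so the count is not independent of that rise. An effect of Il33 loss on Erdr1 or Fgfbp3 was not tested apart from background and stays open.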
